A study of Mus musculus with 4 samples.

How the data were processed

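The data are expression arrays of mouse liver, with 2 FF and 2 KO animals aged 8 weeks. Per the labels' protocols, total RNA was extracted with a column kit, amplified and labelled with biotin in a whole-transcript protocol. The deposited value table holds log2 values made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, with no version named. RMA, as the method is defined, subtracts background, equalises the distributions of all arrays by quantile normalization and summarises the probes of a probe set by median polish. It therefore forces a common distribution on the arrays, so a change in the total amount of RNA per cell cannot be seen, and it compresses the folds of dim probe sets. The log base is not stated in the value table; it was taken from the log2 averages of the authors' other table. That second deposited table gives, per the file headers, the log2 averages of the Alb-cre and f/f groups and a signed linear fold change. It has no p-values, and how its averages were made is not given in the sources used here. Its averages lay a median of 0.67 above those of the value table. Log2 folds of both tables correlated at 0.645 over all probe sets and at 0.922 over the 4689 with a mean level above 6. The tests were therefore run on the value table, and the authors' table served for gene names and as a comparison.

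Gene symbols came from the authors' table alone. Of 41345 probe sets, 29945 had 1 symbol, 1884 had several, 2546 had none, 6944 were not listed in that table, and 26 had a symbol that a spreadsheet had turned into a date. Only probe sets with 1 symbol were tested in the primary comparison, which gave 29432 genes. For the 381 genes with several probe sets of their own the one with the highest mean over all 4 arrays was used. Among called genes 5 had several probe sets, and no gene had probe sets called in opposite directions. Coordinates are those of the RefSeq gene table for GRCm38.p6, the assembly behind the mm10 annotation named in the file header, and 25692 symbols were found in it.

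Groups were taken from the sample labels. The comparison of KO with FF was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), with no block, no weights and no filter on dim genes. With 2 residual and 3.79 prior degrees of freedom the moderated test had 5.79 in total. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called when its adjusted p was under 0.05. A log2 change of at least 1, or 2-fold, was counted separately. In the text each error after ± is the limma standard error of the log2 fold change unless it is named as an SD, and limma gave each adjusted p of a gene.

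The 35 gene lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. The lists held 720 entries, of which 685 were measured, and 26 genes stood in 2 or more lists. Lists were tested with camera from limma at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists. Camera with an estimated correlation and fry served as alternatives. Counts "adjusted over the list alone" use the limma p-values of a list's members with the adjustment made over those members. The genes named are the targeted gene, the 12 largest rises and 12 largest falls among called genes whose KO values both lie outside the FF range, and up to 3 called genes per direction of each list. For a list with no call they are the 2 members with the largest changes. Some genes that this rule names are not reported here. Symbols that begin with Gm and a digit, Mir, Snor, Olfr or Vmn, or end in Rik, were left out of the largest changes, which left out 75 called genes. A few further genes, picked after their values were seen, are Mdm2, Bax, Fas, Trp53, Bbc3, Perp, Rrm2b, Cyp7a1 and those that complete a short count. The 1127 olfactory receptor genes, which liver is not known to express, gave a guide to background, with a median of 1.91 and a 95th percentile of 2.82.

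Alternatives were the replicate number as a block, variance trends with and without robust moderation, median centring, cyclic loess, leaving out the 50% of genes with the lowest means, averaging probe sets, leaving out each array, testing all probe sets, an ordinary 2-sample test, an adjusted p under 0.1, limma's treat against 1.2-fold, and the authors' table. Added after the data were seen were lists without shared members, a 2-fold count without a test, and the inclusion of probe sets with date symbols. The labels give no scan date or batch, so batches could not be checked.

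The fit was tested on simulated data. In 10 simulated sets of 29432 genes with the spread estimated here, 200 genes were changed. Of the 2-fold changes 30.1% were found and of the 4-fold changes 94%, and 4.32% of calls were false. With nothing changed a mean of 0 genes and 0.1 lists were called. Spreads were drawn from the prior that limma fitted, so these rates do not test whether that prior holds for the arrays. Genes were drawn independently of each other, so false list calls that come from correlated genes were not tested. For 10 lists shifted by 0.5 on the log2 scale camera called 100% with its preset correlation, 62% with an estimated correlation, and fry 94%. The permutation test of list medians, run on 100 simulated pairs of lists of 20 independent genes, gave a p under 0.05 in 5% of pairs with no shift. Analyses outside limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.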

Results

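Liver RNA of 4 mice was measured on Affymetrix MoGene 2.0 ST arrays, which carry probe sets along the whole transcript of each gene. The animals were C57BL/6 mice aged 8 weeks, killed around midday without treatment. The groups were FF, the control, with 2 arrays, and KO, a knockout of Gdown1, also with 2 arrays. Gdown1 is the protein encoded by Polr2m and binds RNA polymerase II. The header of the authors' deposited table calls the KO side Alb-cre, and albumin-driven Cre recombinase is commonly used to delete floxed genes in hepatocytes. Each array held log2 values for 41345 probe sets, with medians of 2.92 and 2.90 in FF and 2.88 and 2.90 in KO. Pearson's r over all probe sets was 0.984 between the FF arrays and 0.986 between the KO arrays. Between an FF and a KO array r lay from 0.972 to 0.976, across probe sets that are not independent replicates. The small number of arrays limits the precision of every value below. The labels call the samples of a group biological replicates. Limma p-values of genes rest on the spread between these samples, combined with a spread estimated over all genes. The latter carried 3.79 prior degrees of freedom against 2 residual ones. Camera p-values of lists compare genes with each other at a preset inter-gene correlation of 0.01. They therefore rest on the spread between genes rather than on that between animals. Estimated for each list, the correlation ran from -0.18 to 0.57.

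The comparison of KO with FF asked which liver transcripts differ when Gdown1 is deleted. No group with Cre and an intact Gdown1 was measured, so effects of Cre cannot be told apart from those of the deletion. The targeted gene, Polr2m on chromosome 9 from 71478437 to 71485983 (GRCm38.p6), fell by 1.10 ± 0.12 (SE) on the log2 scale, limma adjusted p = 0.0215. Its level was 7.35 and 7.38 on the FF arrays and 6.35 and 6.18 on the KO arrays, so both KO values lay below both FF values. In the authors' deposited table Polr2m had log2 averages of 7.6 in FF and 6.67 in KO, a signed fold change of -1.91. Whether its probes lie inside the deleted part of the gene was not given in the sources used here. Whole liver also holds cells other than hepatocytes.

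The largest rises were in Cyp2b9 and Cdkn1a and the largest falls in Elovl3, Slco1a1 and Hsd3b5. Cyp2b9, a cytochrome P450 found mainly in female mouse liver, rose from 2.87 ± 1.04 to 10.31 ± 0.14 (log2 mean ± SD, n = 2 each). That is a log2 fold change of 7.44 ± 0.45 (SE), with a limma adjusted p of 0.00506. Its FF arrays lay at 2.14 and 3.61, the first under the background guide of 2.82 explained below, so the size of this change is rough, from 6.70 to 8.17 with any single array left out. Cdkn1a, which encodes a cyclin-dependent kinase inhibitor induced by p53, rose by 5.30 ± 0.19, or 39.3-fold, from 4.44 to 9.74 (limma adjusted p = 0.00135). Elovl3, a fatty acid elongase, fell by 5.95 ± 0.15 from 9.24 to 3.29 (limma adjusted p = 0.000403). Slco1a1, an organic anion transporter of the hepatocyte membrane, fell by 5.58 ± 0.40 from 10.48 to 4.90 (limma adjusted p = 0.00783). Hsd3b5, a steroid-metabolising enzyme, fell by 5.51 ± 0.65 from 8.80 to 3.29 (limma adjusted p = 0.0252). Its KO arrays lay at 2.22, under the guide, and 4.36, and its log2 fold change ran from -6.58 to -4.44 with any single array left out, so its size is rough as well; that of Slco1a1 ran from -6.23 to -4.93.

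In total, 522 of 29432 genes passed a limma adjusted p of 0.05, of which 293 rose and 229 fell. At least a 2-fold change was seen in 351 of them, 189 higher and 162 lower in KO. Both KO arrays lay on the same side of both FF arrays for 13719 of the 29432 genes, against 33.3% by chance; with so few arrays the test hardly passes a gene otherwise, and the 522 are all among them. At an unadjusted p under 0.05 there were 4998 genes. The smallest called log2 change was 0.72, so smaller changes were not resolved. Of the 522 genes, 517 had the same direction in the authors' deposited table, and of the 351 with at least a 2-fold change 274 were at least 2-fold in the same direction there. Without any single array, limma called 0 genes (3364 to 3958 at an unadjusted p under 0.05), since 1 array then stands for a whole group. With all probe sets tested, named or not, 42 probe sets passed, and an ordinary 2-sample test without moderated variances passed 1 gene.

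**Figure D1:**
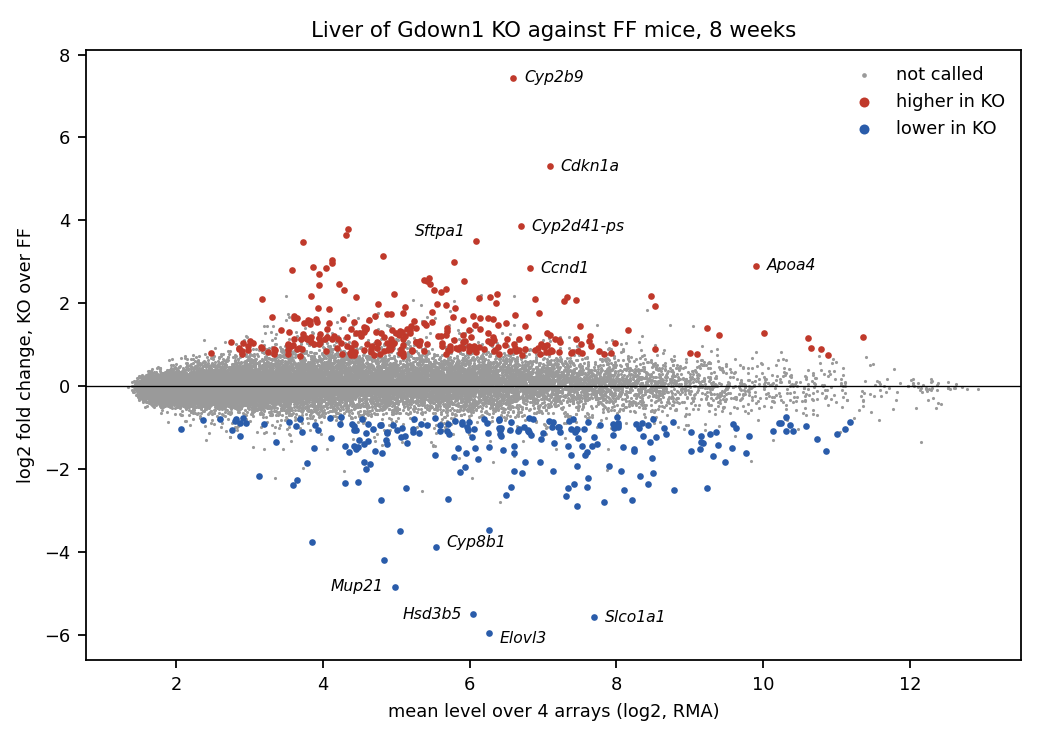
Each point is a gene, with its mean log2 level over 4 arrays on the horizontal axis and its log2 fold change, KO over FF, on the vertical axis. Red points are the 293 genes that rose and blue points the 229 that fell, from Cyp2b9 at 7.44 to Elovl3 at -5.95.

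Several of the other large rises were in genes with little signal in FF liver. Cyp2b13, another cytochrome P450 of female liver, rose by 3.78 ± 0.21 from 2.45 to 6.23 (limma adjusted p = 0.00498). Tnfrsf10b, a death receptor for the ligand TRAIL, rose by 3.65 ± 0.13 from 2.49 to 6.14 (limma adjusted p = 0.00121). Ipw, a non-coding transcript of the imprinted region linked to Prader-Willi syndrome, rose by 3.48 ± 0.12 from 1.99 to 5.47 (limma adjusted p = 0.00121). These FF means lie under 2.82, the level below which 95% of 1127 olfactory receptor genes lay, and folds from such means understate the change. Sftpa1, a surfactant protein best known from lung, rose by 3.49 ± 0.27, and the P450 pseudogene Cyp2d41-ps rose by 3.86 ± 0.24. Apoa4, an apolipoprotein, rose by 2.90 ± 0.28 from 8.45 to 11.35, and Ccnd1, which encodes cyclin D1, rose by 2.84 ± 0.33 from 5.39 to 8.24. Gria3, a glutamate receptor subunit, rose by 2.98 ± 0.17, Eda2r by 2.98 ± 0.23 and Ifi27l2b by 3.04 ± 0.44. The FF means of Eda2r and Ifi27l2b, 2.64 and 2.61, also lie under 2.82, so these folds understate the change too.

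The other large falls included major urinary protein genes. Mup21 fell by 4.84 ± 0.11 from 7.40 to 2.56 (limma adjusted p = 0.000403), and the pseudogenes Mup-ps12 and Mup-ps16 fell by 3.76 ± 0.28 and 3.51 ± 0.21. Members of this family have near-identical sequences, so their probe sets may share transcripts. The adhesion receptor gene Adgrf1 fell by 4.19 ± 0.17, the lectin-like gene Clec2h by 2.73 ± 0.12 and the pseudogene Adh6-ps1 by 2.90 ± 0.19. Hsd17b6, a hydroxysteroid dehydrogenase, fell by 2.80 ± 0.20 from 9.23 to 6.43. The KO means of Mup21, Mup-ps12 and Adgrf1, at 2.56, 1.98 and 2.74, lie under 2.82, so these falls understate the change.

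**Figure D2:**
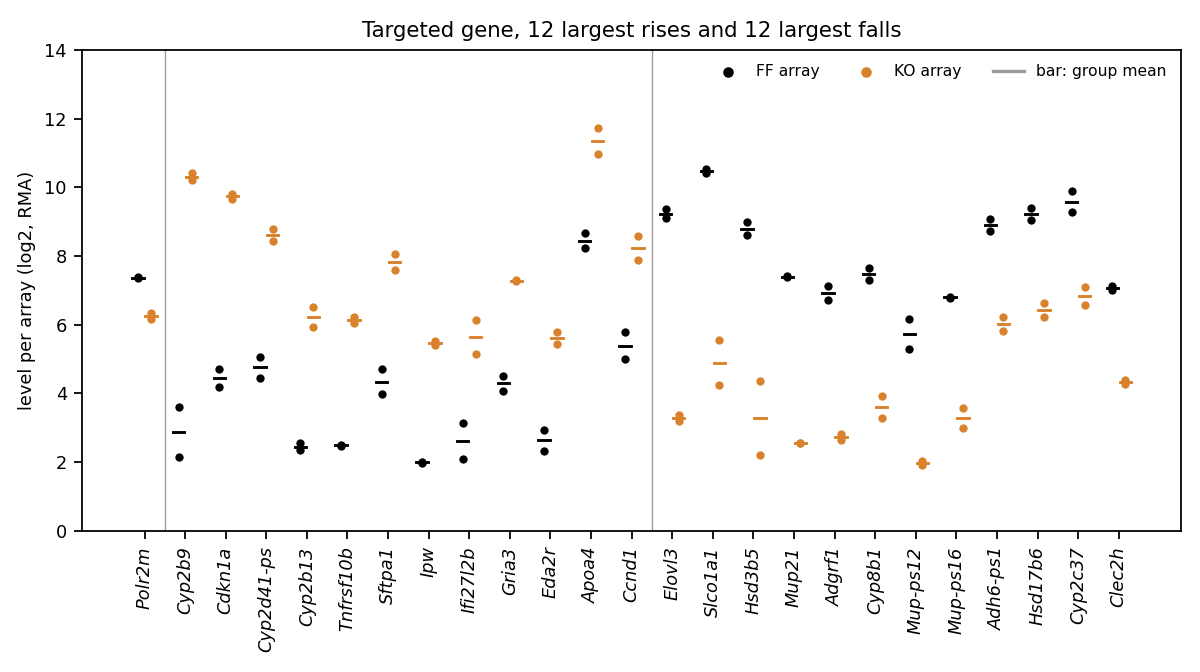
Log2 level on each of the 4 arrays for Polr2m, the 12 largest rises and the 12 largest falls, with FF arrays in black, KO arrays in orange and a bar at each group mean. In each gene shown, both KO values lie on the same side of both FF values.

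The p53 target list showed the largest upward shift of the 35 gene lists. Of 28 measured members 16 rose and 0 fell (limma, over all genes), the other 12 did not pass, and 25 rose when adjusted over the list alone. The median log2 fold change was 1.29, with a camera adjusted p of 1.65e-27; the adjusted p = 0.350 with an estimated correlation. Besides Cdkn1a, Tnfrsf10b and Eda2r, the genes that rose included Mdm2, which encodes the ubiquitin ligase of p53, Bax, a promoter of apoptosis, and the death receptor gene Fas. These 3 were picked after their values were seen, with log2 fold changes of 1.45 ± 0.15, 1.54 ± 0.19 and 1.27 ± 0.13. Trp53 itself, also picked afterwards, rose by 0.85 ± 0.12 (limma adjusted p = 0.0362). Bbc3, Perp and Rrm2b were among the members that did not pass, with log2 fold changes of -0.09, 0.12 and 0.35.

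Few cell cycle genes passed the test. In the mitosis and G2/M list 1 of 30 genes rose, Ect2, a regulator of cytokinesis, at 0.93 ± 0.12, and 5 rose when adjusted over the list alone. Its median was 0.28 with a camera adjusted p of 4.54e-06, and the adjusted p = 0.366 with an estimated correlation. The DNA replication and S phase list was not called, with a median of 0.05 over 37 genes and a camera adjusted p of 0.394. Its 1 called gene, Tk1 for thymidine kinase, fell by 1.22 ± 0.15, and the same 1 gene fell when adjusted over the list alone. Of the fetal liver and regeneration list, 3 of 17 genes rose, namely Ccnd1, Lpl, a lipoprotein lipase gene, at 2.09 ± 0.21 and Cd24a at 1.40 ± 0.22. The counts adjusted over the list alone were 5 higher and 1 lower. The median was 0.30, with a camera adjusted p of 0.00168 and an adjusted p = 0.366 with an estimated correlation, and it was 0.46 on KO array 1 and 0.15 on KO array 2 against the FF mean.

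The list of RNA polymerase II, which Gdown1 binds, and of pausing and related factors shifted up. Polr2a, the largest subunit of the polymerase, rose by 1.45 ± 0.13 from 6.77 to 8.23 (limma adjusted p = 0.0120). Supt5, part of an elongation factor that acts in pausing, rose by 0.85 ± 0.13 (limma adjusted p = 0.0408). These were the 2 called genes among 39, with 3 higher when adjusted over the list alone and 0 lower. The list median was 0.22, with a camera adjusted p of 4.54e-06 and an adjusted p = 0.350 with an estimated correlation.

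The list of male-biased liver genes shifted down and that of female-biased genes up. Of 16 male-biased genes 5 fell and 0 rose, namely Elovl3, Slco1a1, Hsd3b5, Ugt2b38 and Nudt7, and 8 fell when adjusted over the list alone. The median was -1.09, with a camera adjusted p of 1.44e-07 and an adjusted p = 0.366 with an estimated correlation. The median of KO array 1 against the FF mean was -1.42 and that of KO array 2 was -0.62. Of 18 female-biased genes 4 rose and 0 fell, namely Cyp2b9, Cyp2b13, Prom1 at 1.69 ± 0.14 (FF mean 2.76, under 2.82) and Fmo2 at 1.19 ± 0.18. With p adjusted over the list alone, 6 rose and 1 fell, Cyp39a1 at -1.45. By mean, 11 of the 18 were higher in KO and 7 lower. Their median was 0.22, or 0.14 without FF replicate 2, with a camera adjusted p of 0.00147 and an adjusted p = 0.462 with an estimated correlation. Prom1 also stands in the ductular list. The list of Y-linked genes and Xist was not called, with a median of -0.08 over 5 genes, 0 of them called by limma over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05), and a camera adjusted p of 0.493. Eif2s3y lay at 6.73 in FF and 6.51 in KO, and Kdm5d at 4.58 and 4.23. Xist, which is expressed from the inactive X chromosome, had a log2 fold change of 0.14 and lay below 2.82 in both groups.

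**Figure D3:**
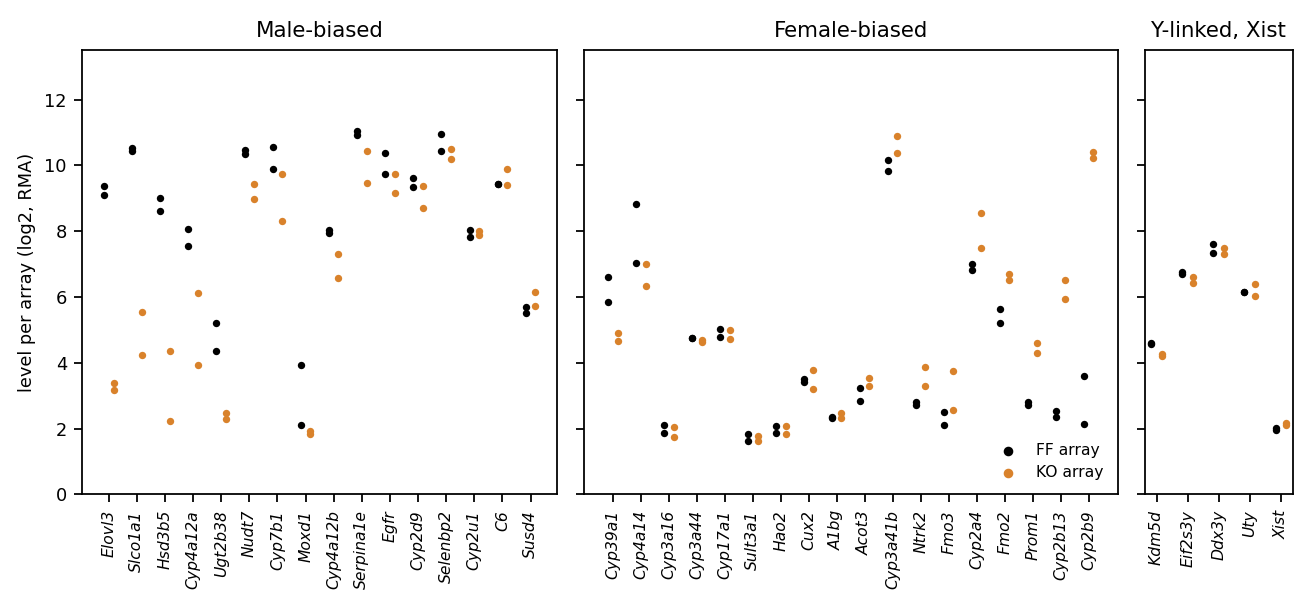
Log2 level on each array, FF in black and KO in orange, for the 16 male-biased genes, the 18 female-biased genes, and the Y-linked genes with Xist, sorted by fold change within a panel. Elovl3, Slco1a1 and Hsd3b5 lie far lower in KO, while Cyp2b9 and Cyp2b13 lie far higher.

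Bile acid genes shifted down. Cyp8b1, the enzyme that directs bile acid synthesis towards cholic acid, fell by 3.88 ± 0.24 from 7.47 to 3.60 (limma adjusted p = 0.00506). Baat, which joins bile acids to amino acids, fell by 2.43 ± 0.12 from 8.82 to 6.39 (limma adjusted p = 0.00372). Of 19 genes 5 fell, which also include Slco1a1, Slc27a5 and Cyp27a1, and 1 rose, the canalicular exporter gene Abcc2, at 0.75 ± 0.12. Adjusted over the list alone, 9 fell and 2 rose. The median was -0.54, with a camera adjusted p of 0.000166 and an adjusted p = 0.350 with an estimated correlation. Cyp7a1, the rate-limiting enzyme of the classic pathway, had a log2 fold change of -0.13 and did not pass.

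Xenobiotic metabolism genes also shifted down, with the large exception of Cyp2b9. Of 23 genes 6 fell and 1 rose, and 12 fell and 4 rose when adjusted over the list alone. The cytochrome P450 genes Cyp2c37, Cyp2c50 and Cyp2c54 fell by 2.76 ± 0.25, 2.09 ± 0.15 and 1.53 ± 0.12. Like the Mup genes, the Cyp2c genes form a family of close paralogs. The list median was -0.53, with a camera adjusted p of 0.000106 and an adjusted p = 0.350 with an estimated correlation.

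**Figure D4:**
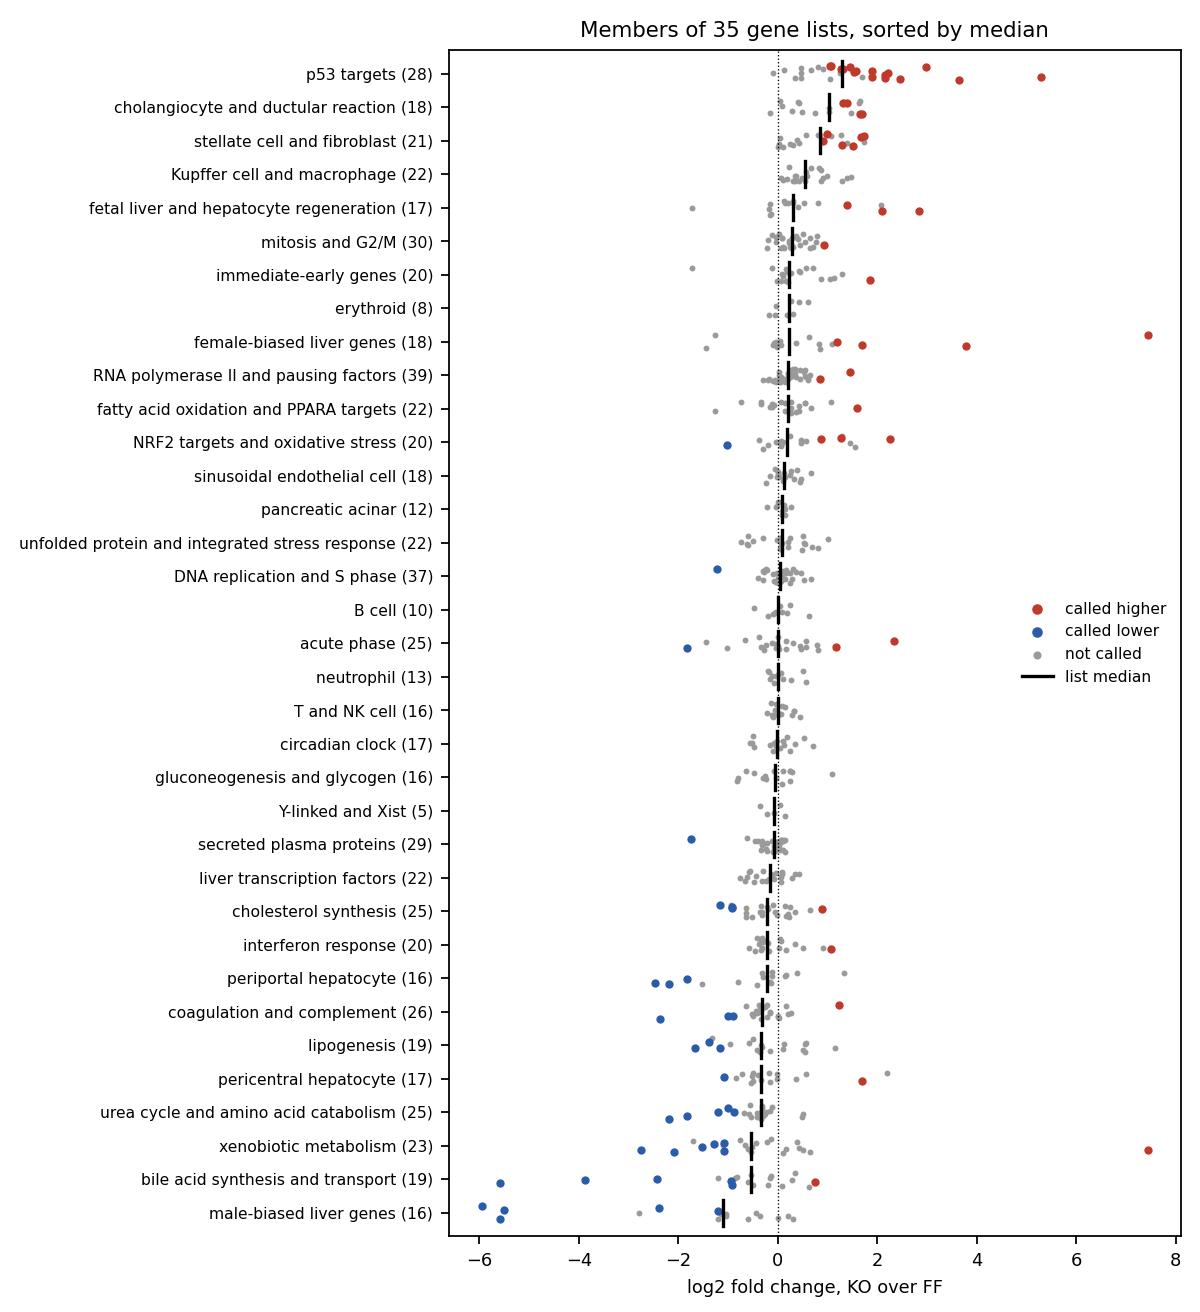
Log2 fold change of each measured member of the 35 gene lists, with the list median as a black bar and the number of members in brackets. Members that rose are red and those that fell are blue; medians run from -1.09 for male-biased genes to 1.29 for p53 targets.

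Genes of amino acid catabolism shifted down. Hal, which starts histidine degradation, fell by 2.18 ± 0.21 from 9.41 to 7.22 (limma adjusted p = 0.0151), and Amdhd1, a later step, fell from 8.95 to 7.76. Sds, a serine dehydratase, fell by 1.83 ± 0.20. Uroc1 of the histidine pathway and Haao of tryptophan breakdown were the other called genes, so that 5 of 25 fell and 0 rose. Ftcd, a last step of histidine degradation, was at 0.50 and did not pass over all genes. There were 11 falls and 2 rises adjusted over the list alone. The median was -0.35, with a camera adjusted p of 2.53e-08 and an adjusted p = 0.350 with an estimated correlation. The gluconeogenesis and glycogen list was not called (median -0.05 over 16 genes, camera adjusted p = 0.875). None of its genes passed limma over all genes (4 at an unadjusted p under 0.05), and adjusted over the list alone 1 rose and 3 fell. The largest changes there were Pgm1 at 1.09 and Tat at -0.81.

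Lipid genes changed in both directions. In the lipogenesis list 3 of 19 genes fell, among them the acetyl-CoA carboxylase gene Acacb at -1.39 ± 0.18 and the desaturase gene Scd1 at -1.16 ± 0.15. When adjusted over the list alone, 9 fell and 4 rose. The median was -0.33, with a camera adjusted p of 0.0257 and an adjusted p = 0.566 with an estimated correlation. In the cholesterol synthesis list 3 of 25 genes fell and 1 rose. Among them Insig1 and Fdps fell by 1.17 ± 0.14 and 0.93 ± 0.13, and Lss, the lanosterol synthase gene, rose by 0.89 ± 0.12. Lss had a log2 fold change of -0.08 in the authors' deposited table. Adjusted over the list alone, 9 fell and 2 rose. The median was -0.21, with a camera adjusted p of 0.0167 and an adjusted p = 0.479 with an estimated correlation. In the list of fatty acid oxidation and PPARA targets 1 of 22 genes rose, the thioesterase gene Acot1 at 1.59 ± 0.24, and adjusted over the list alone 7 rose and 1 fell. Its median was 0.20, with a camera adjusted p of 0.0329 and an adjusted p = 0.462 with an estimated correlation. Camera no longer called the lipogenesis list without KO replicate 1 (adjusted p = 0.307) or the cholesterol list without KO replicate 2 (adjusted p = 0.0607). The fatty acid oxidation call ended without FF replicate 1 (median 0.08) or KO replicate 2 (median 0.11). It also ended with cyclic loess (camera adjusted p = 0.0827) and without the dimmer genes (0.249).

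Among secreted proteins, coagulation and complement genes shifted down, and the median of plasma proteins lay near 0. In the plasma protein list 1 of 29 genes fell, Itih3, an inter-alpha-trypsin inhibitor chain, at -1.74 ± 0.20, and 2 fell when adjusted over the list alone. The median was -0.08, with a camera adjusted p of 0.0413 and an adjusted p = 0.366 with an estimated correlation. That call ended without FF replicate 2, KO replicate 1 or KO replicate 2 (camera adjusted p = 0.183, 0.0568 and 0.0687) and with cyclic loess (0.106). In the coagulation and complement list F11, the gene of coagulation factor XI, fell by 2.37 ± 0.20, Masp1 by 1.01 ± 0.13 and C9 by 0.90 ± 0.12, while Mbl2, a mannose-binding lectin, rose by 1.24 ± 0.13. Of its 26 genes, 5 fell and 1 rose adjusted over the list alone. The median was -0.33, with a camera adjusted p of 0.00016 and an adjusted p = 0.454 with an estimated correlation, and it was -0.37 on KO array 1 and -0.20 on KO array 2 against the FF mean. The acute phase list was not called, with a median of 0.01 over 25 genes and a camera adjusted p of 0.555. Its members Lcn2 and Serpina3n rose by 2.34 ± 0.26 and 1.18 ± 0.13, and Crp fell by 1.83 ± 0.12. Adjusted over the list alone, 3 rose and 3 fell.

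Genes that mark hepatocyte position in the lobule shifted down on both sides. In the periportal list 3 of 16 genes fell, namely Pigr, a receptor that carries immunoglobulin into bile, at -2.46 ± 0.11, with Hal and Sds, and 6 fell and 1 rose when adjusted over the list alone. The median was -0.22, with a camera adjusted p of 0.00315 and an adjusted p = 0.366 with an estimated correlation. In the pericentral list Cyp1a2 fell by 1.08 ± 0.13 and Rhbg, an ammonium transporter gene, rose by 1.69 ± 0.18, among 17 genes, and adjusted over the list alone 8 fell and 3 rose. The median was -0.34, with a camera adjusted p of 0.0352 and an adjusted p = 0.366 with an estimated correlation. The pericentral call ended without FF replicate 2 (median -0.31) or KO replicate 2 (median -0.32). Without members that other lists share neither list was called. The pericentral median was then -0.25 (camera adjusted p = 0.307) and the periportal median -0.12 (camera adjusted p = 0.119). Of 22 liver transcription factors 0 were called by limma over all genes, 9 had an unadjusted p under 0.05 and 4 fell when adjusted over the list alone. Their median was -0.16, with a camera adjusted p of 0.0219 and an adjusted p = 0.462 with an estimated correlation. Foxa1 and Nr1i3 had the largest changes, -0.75 and -0.65. With any single array left out Foxa1 ran from -1.03 to -0.47 and Nr1i3 from -0.73 to -0.58. The call of the transcription factor list ended without FF replicate 2 (median -0.10) or KO replicate 1 (median -0.18).

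Among the stress response lists, NRF2 targets shifted up. G6pdx, the entry enzyme of the pentose phosphate pathway, rose by 2.27 ± 0.13, the epoxide hydrolase gene Ephx1 by 1.27 ± 0.13 and the sulfiredoxin gene Srxn1 by 0.87 ± 0.14, while the glutathione transferase gene Gstp1 fell by 1.03 ± 0.14. Of its 20 genes, 7 rose and 2 fell adjusted over the list alone. The median was 0.18, with a camera adjusted p of 0.00438 and an adjusted p = 0.546 with an estimated correlation. Its call ended without KO replicate 1 (median 0.06, camera adjusted p = 0.0643), and without KO replicate 2 the median was 0.34. In the immediate-early list 1 of 20 genes rose, Gadd45b at 1.85 ± 0.15, and 2 rose when adjusted over the list alone. The median was 0.23, with a camera adjusted p of 0.00147 and an adjusted p = 0.534 with an estimated correlation, and the call ended without KO replicate 2 (median 0.04, camera adjusted p = 0.212). Without KO replicate 1 the median was 0.57 (camera adjusted p = 2.07e-08) and without FF replicate 2 it was 0.35. The lists of the unfolded protein and integrated stress response, the circadian clock and the interferon response were not called (camera adjusted p = 0.381, 0.951 and 0.385). Their medians were 0.08, -0.02 and -0.22. The interferon list had 1 gene that rose, Oasl2 at 1.07 ± 0.17, also when adjusted over the list alone, and camera called the list as shifted down without FF replicate 1 (adjusted p = 0.0185). The unfolded protein list was called as shifted up without KO replicate 1 (camera adjusted p = 0.0413). Limma called 0 genes of the unfolded protein list over all genes, 7 at an unadjusted p under 0.05, and 2 fell adjusted over the list alone. Of the circadian genes it called 0 in either way, 3 at an unadjusted p under 0.05, and Npas2 and Usp2 had the largest log2 fold changes, 0.72 ± 0.32 and -0.56 ± 0.39, which ran from 0.22 to 1.21 and from -1.10 to -0.02 with any single array left out.

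Marker lists of stellate cells, ductular cells and macrophages shifted up. In the stellate cell and fibroblast list 6 of 21 genes rose and 0 fell, led by the metalloprotease gene Mmp2 at 1.73 ± 0.25 and the collagen genes Col3a1 at 1.68 ± 0.15 and Col1a1 at 1.51 ± 0.12. Adjusted over the list alone, 12 rose. The median was 0.84, with a camera adjusted p of 1.51e-11 and an adjusted p = 0.364 with an estimated correlation. In the cholangiocyte and ductular list 4 of 18 genes rose, namely Prom1, Tspan8 at 1.64 ± 0.20, Cd24a and Krt23, and 11 rose when adjusted over the list alone. The median was 1.03, with a camera adjusted p of 9.85e-11 and an adjusted p = 0.366 with an estimated correlation. In the Kupffer cell and macrophage list 0 of 22 genes were called by limma over all genes (10 at an unadjusted p under 0.05), 3 rose when adjusted over the list alone, and all 22 had a higher mean in KO. The median was 0.56, with a camera adjusted p of 3.1e-08 and an adjusted p = 0.454 with an estimated correlation. The macrophage median was 0.89 for KO array 1 against the FF mean and 0.24 for KO array 2. Spp1, at 1.48 ± 0.36, and Marco, at 1.38 ± 0.58, had the largest changes and did not pass. With any single array left out Marco ran from 0.42 to 2.35 and Spp1 from 0.93 to 2.02.

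Other cell type marker lists had smaller medians, some of them in lists with levels near background. The sinusoidal endothelial list had a median of 0.13 over 18 genes, with a camera adjusted p of 0.0174 and an adjusted p = 0.366 with an estimated correlation. None of its genes was called by limma over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05), and Lyve1 and Stab1 had the largest log2 fold changes, 0.66 and 0.47. That call ended without FF replicate 2 or KO replicate 1 (camera adjusted p = 0.0745 and 0.0775), with cyclic loess (0.144) and without the dimmer genes (0.155). The erythroid list had a median of 0.22 over 8 genes, with a camera adjusted p of 0.0465 and an adjusted p = 0.366 with an estimated correlation. No erythroid gene passed limma over all genes, 2 had an unadjusted p under 0.05, 2 rose when adjusted over the list alone, and Hba-a2, a globin gene, was at 0.61 ± 0.12. The erythroid call ended without FF replicate 1 (median 0.19) or KO replicate 2 (median 0.09). It also ended with median centring (camera adjusted p = 0.0508), with cyclic loess (0.0615) and without members that other lists share (0.0508). The lists of T and NK cells, B cells, neutrophils and pancreatic acinar cells were not called (camera adjusted p = 0.402, 0.8, 0.546 and 0.381). Their medians were 0.00, 0.01, 0.01 and 0.08, and limma called none of their genes, over all genes or adjusted over the list alone, with 1, 1, 1 and 0 genes at an unadjusted p under 0.05. The largest changes were Trac at 0.45 ± 0.23, Ighm at 0.63 ± 0.57, Retnlg at 0.57 ± 0.14 and Ctrb1 at 0.27 ± 0.11. With any single array left out Ighm ran from -0.28 to 1.54 and Trac from 0.12 to 0.79, so these 2 rest on single arrays.

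Across the 35 lists camera with its preset correlation called 24, of which 13 shifted up and 11 down. With a correlation estimated for each list it called 0, with 5 lists at an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move on balance in a single direction, called 4, namely p53 targets, RNA polymerase II factors, bile acid genes and xenobiotic genes, each with an adjusted p of 0.0458. Median, mean and test had the same sign in every called list.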

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

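Of the probe sets outside the primary test, 8 passed limma when all 41345 were tested together. There were 6 such probe sets that the authors' gene table does not list, 4 higher and 2 lower in KO, and 2 that it names for several genes, 1 higher and 1 lower. The largest rise was 3.01 on the log2 scale, in an unlisted probe set that went from 2.42 and 2.33 on the FF arrays to 5.44 and 5.32 on the KO arrays (limma adjusted p = 0.0269). The largest fall, by 3.15, appeared with identical values in an unlisted probe set and in a probe set named for several genes (limma adjusted p = 0.0419). Without a single gene name these signals were not assigned to a gene. Among the 2546 probe sets with no symbol and the 26 with a date for a symbol limma called 0, with 216 and 3 at an unadjusted p under 0.05.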

How the results depend on the processing

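The replicate number as a block, which pairs arrays only by number (correlation of same-number deviations -0.0036), gave 30 genes (17 higher, 13 lower), all at least 2-fold and all among the 522; it ended the calls of the plasma protein and erythroid lists (camera adjusted p = 0.0550 and 0.0506) and no other list's. Without each array limma called 0 genes, with or without the 2-fold threshold; prior degrees of freedom dropped from 3.79 to between 2.41 and 2.61 and 1 residual degree was left. Trend with robust moderation called 975 (575 higher, 400 lower), the fit without the dimmer genes, which tests fewer genes, 850 (501 and 349), and an adjusted p under 0.1, a looser threshold, 1235 (752 and 483). Median centring gave 476 rises. Testing all probe sets gave 42 calls (22 and 20) with 2.69 prior degrees of freedom. The ordinary test gave 1 (0 higher, 1 lower; 3391 genes at an unadjusted p under 0.05), and treat against 1.2-fold gave 209 (104 and 105). Of the lists, an estimated correlation called 0 (0 up, 0 down) and fry 4 (2 up, 2 down). In simulated lists of independent genes the estimated correlation also found fewer shifts, 62% against 100%. Lists of correlated genes were not simulated, so this does not decide between the settings. Some called lists, such as xenobiotic, RNA polymerase II and bile acid genes, had estimated correlations under the preset 0.01 (-0.022, -0.011 and 0.002). Their camera adjusted p still rose to 0.350 with an estimated correlation. A higher correlation therefore does not account for the end of these calls. The causes of the differences were not tested. Counted without a test, the authors' table had 377 genes at least 2-fold lower against 238 in the value table, and of 92 log2 fold changes of named genes 40 moved there by more than the standard error of a difference between 2 such changes, 51 did not and Lss was reversed at -0.084. Calls of trend alone, cyclic loess, averaged probe sets, date symbols and lists without shared members stayed within 1.5 times the primary counts. Signal over background limits dim genes: 31 called genes lay below 2.82 in FF and 18 in KO, 2 of them in both.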

Other observations

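The tests of hepatocyte share, of shared members, of sex, of plasma protein genes, of STAT5 targets and of neighbouring genes below were chosen after the results they bear on were seen, as were the gene families and single genes described next.

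Of 13 gene families camera called 9 with its preset correlation and 0 with an estimated one. Of 11 major urinary protein genes 5 fell and 0 rose, with a median log2 fold change of -1.35 and a camera adjusted p of 2.45e-11. The adjusted p = 0.257 with an estimated correlation. Collagen genes, some of which stand in the stellate list, had 5 rises among 44 and a median of -0.01 (camera adjusted p = 0.0277, upward), and the median was 0.00 with median centring or cyclic loess. Of 17 mitochondrial tRNA genes 2 fell: mt-Tf fell by 2.47 ± 0.15 and mt-Tr fell by 0.92 ± 0.12 (limma adjusted p = 0.00498 and 0.0292). Among those that did not pass, mt-Tc and mt-Ty went the other way, with log2 fold changes of 2.17 ± 0.64 and 1.83 ± 0.53 (limma adjusted p = 0.173 and 0.166). Their KO arrays lay far apart, at 6.65 and 8.73 for mt-Tc and at 8.59 and 10.07 for mt-Ty. The median of the 17 was -0.64, with a camera adjusted p of 5.08e-06 and an adjusted p = 0.257 with an estimated correlation. The mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 had log2 fold changes of -0.02 and -0.10 and did not pass. Ribosomal protein genes had a median of -0.11 over 147 and histone genes one of 0.06 over 58 (camera adjusted p = 0.0138 and 0.00845).

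Several called genes outside the lists were picked, after their values were seen, for their size, setting or function. Igfbp2, an insulin-like growth factor binding protein, fell by 1.94 ± 0.13, Nnmt, a nicotinamide methyltransferase, by 1.99 ± 0.20 and the long non-coding RNA Neat1 by 1.59 ± 0.16. Sftpa1, which rose by 3.49, lies on chromosome 14 from 41131788 to 41136373, beside Mat1a from 41105012 to 41124428 (GRCm38.p6), whose FF level was 11.20. Hhex, a transcription factor of early liver development, fell by 1.24 ± 0.12. Nfe2l2, which encodes NRF2, rose by 1.35 ± 0.15 (limma adjusted p = 0.0214). The receptor gene Osmr, the growth factor gene Hgf and the receptor gene Tgfbr2 rose by 1.21 ± 0.13, 1.03 ± 0.12 and 0.96 ± 0.12. In the authors' deposited table they were at 0.92, 0.93 and 0.43 on the log2 scale. No list of such signalling genes was tested. In the imprinted region on chromosome 7 Ipw rose while Ndn, Magel2, Mkrn3, Peg12 and Ube3a did not pass, with log2 fold changes of -0.17, -0.02, 0.21, -0.04 and 0.01. Magel2 and Mkrn3 lay under 2.82 in both groups, and Ndn and Peg12 near it, at 3.06 and 3.15 in FF. In the authors' deposited table the log2 fold changes were 0.93, 0.19, 0.08, 0.56 and -0.23 in the same order. A rise confined to Ipw is therefore not shown.

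The stellate and ductular lists shifted up. A lower share of hepatocytes in the KO samples would raise other cell types alike, if their marker levels per cell stayed the same. The stellate median exceeded the endothelial median by 0.709 (permutation p = 0.00068, two-sided), with gaps of 0.752 on KO array 1 and 0.539 on KO array 2. This argues against a lower hepatocyte share as the whole cause only if endothelial cells kept their marker levels, which was not tested. Genes are not independent replicates, so this p describes the lists rather than the animals. The stellate list shares no member with another list, and without its 4 shared members the ductular median dropped from 1.03 to 0.62 but camera still called the list (adjusted p = 4.35e-07), so shared members do not account for all of its shift. What stays open is a change in number or activity of stellate and ductular cells, and whether KO hepatocytes themselves express these genes, which may be a hypothesis for sorted cells.

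Of 16 male-biased genes 5 fell, and of 18 female-biased genes 4 rose. Female KO animals are argued against by the 4 Y-linked genes, whose mean level was 6.09 in KO and 6.23 in FF, far above the olfactory receptor guide of 2.82 on each array. The male-biased median lay 1.015 below that of plasma proteins (a difference of -1.015, permutation p = 4e-05, two-sided). This argues against a fall no larger than that of plasma proteins as the whole cause of the male-biased falls. The plasma protein list moved little, with a median of -0.08. Other hepatocyte lists had lower medians, -0.54 for bile acid, -0.53 for xenobiotic and -0.35 for amino acid genes. The male-biased median was not tested against these, so a wider fall of hepatocyte transcripts stays open. Lower growth hormone signalling through STAT5, a candidate explanation, was not decided: Socs2, Cish and Igf1 had a mean log2 fold change of -0.328, and none was called. Shared probes between Cyp2b9 and Cyp2b13, which are close paralogs, also stay open for the rises of that pair. They do not bear on the other called rises, Prom1 at 1.69 and Fmo2 at 1.19.

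Among the genes at background in FF that have a position in the gene table, 26 rose in KO, such as Tnfrsf10b and Ipw, and read-through from a neighbouring highly expressed gene, called bright here at a mean level of at least 9 in either group, would raise those close by. The median of 139 background genes within 10 kb of a bright gene exceeded that of 10836 over 100 kb away by 0.01 (permutation p = 0.515, two-sided) and differed by -0.009 from that of 1214 near genes of level 5 to 7 (permutation p = 0.622), which leaves a general shift undecided. Of the 139, Cgref1, Adam2 and Trim69 rose, 3 in all, against 19 of the 10836 (Fisher's exact test, p = 0.00257). Among genes with a mean under 4 over all 4 arrays 5 of 231 near a bright gene rose against 47 of 15497. These 5 hold the same 3 genes with E030003E18Rik and Ffar4, so this count is not separate support. A rise in KO also changes the mean by which these genes were classed. Read-through may apply to those 3 and to genes above background in FF such as E030003E18Rik, Ffar4 and Sftpa1, the last 7360 bases from Mat1a. It stays open, since the gene table gives no strand. Other such genes that rose were Cyp2d41-ps, Bax, Fads3 and Tcta, with gaps to a bright gene of 7985, 6053, 2652 and 1 bases. E030003E18Rik has no gap to a bright gene, so its signal may be that gene's own transcript. Of the 26 genes 19 lay over 100 kb from any bright gene, 3 of them within 10 kb of a gene of level 5 to 7.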
